A study of Homo sapiens with 12 samples.

How the data were processed

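RNA from 12 cultures of CCL210, a human adult fibroblast line, was measured on an Affymetrix 3' expression array, with 3 arrays in each of 4 groups. Per the labels, cells were plated at 250000 per well in 10% serum, kept without serum for 48 h, given TGF-β1 (2 ng/ml) or none for 24 h and, after the medium was removed, PGE2 (500 nM) or none for a further 48 h, and 250 ng of RNA was used. The labels state that RNA came from independent experiments, but where separate cultures are not stated the p-values measure the spread between these samples. The deposited values are log2 intensities that the authors obtained by RMA with the affy package, per the submitters' processing notes, which give no versions. Array values lay between 3.15 and 13.5, and none was transformed again.

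Of the 49386 probe sets, 93 were array controls, of which 6 also named genes and are counted again below, 45259 named 1 gene symbol, 1327 named several and 2713 named none. Of those with 1 symbol, 45178 were found in the reference by gene identifier and 81 were not. Each of the 18239 genes was measured by the probe set with the highest mean over the 12 arrays among its probe sets, and 11823 genes had more than 1. Probe sets with several symbols or none were tested apart from the genes. Listed genes without a probe set were not analysed here. Arrays give no counts, so precision is given by the standard errors. No detection calls were given. The 23 nonspecific control probe sets, used as a background level only after the data were seen, had means of 3.28 to 8.08. Their median was 3.74 and their 95th percentile 5.79. Of 371 called values of named genes between 2 groups, 96 had a lower mean under that percentile and may be only lower bounds. The median of all probe sets lay between 5.25 and 5.38 on each array, so a mean under 5.79 is not shown to lie at the floor. Within a group, arrays correlated at 0.993 or more.

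Linear models were fitted with limma 3.58.1 in R 4.3.3 to all 12 arrays with 4 group means and 8 residual degrees of freedom, with moderated variances and Benjamini-Hochberg adjustment over the 18239 genes in each comparison. A gene was called at an adjusted p under 0.05. The comparisons were TGF-β1 against control, TGF-β1 then PGE2 against TGF-β1, PGE2 against control, TGF-β1 then PGE2 against control, and the interaction, which is the PGE2 effect after TGF-β1 minus that without it. Gene lists were tested with camera from limma with a preset correlation of 0.01, adjusted over the 24 lists, and again with the correlation estimated from the residuals, with fry and with a replicate block. Camera tests a list against the other genes, while fry tests it against no change. Members were counted by the adjustment over all genes and by adjustment over the list alone. For every list past the threshold the median, the mean and the test had the same sign (41 of 120 list comparisons), while they differed for 26 of those not past it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

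The comparisons, alternatives, 24 lists and the rule for naming genes were fixed before the data were examined. The rule took, in each comparison, the 6 largest rises and 6 largest falls among called genes whose 3 arrays of one group all lay above the 3 of the other, which chance gives in 10% of genes for 3 against 3, or 4 each way for the interaction without that condition. It added up to 4 called members of each list with at least 2 called members, and a panel of 12 genes whatever their values. Members in a direction taken by 3 or fewer of a list, where the rule did not take them, were chosen after their values were seen. Of 94 such members, 35 lost their call without at least 1 array, and those are left unnamed or given with the array that moved them furthest. The lists were contractile and cytoskeletal genes, collagens, matrix glycoproteins, collagen processing, TGF-β targets, genes responding to cyclic AMP, prostaglandin genes, cell cycle, amino acid synthesis, unfolded protein response, cytokines, interferon-stimulated genes, cholesterol synthesis, metalloproteinases and plasminogen system, Wnt pathway, lipid storage, apoptosis, integrins and adhesion, oxidative stress, hyaluronan and growth factors, and epithelial, endothelial, leukocyte and pericyte markers.

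Whether replicate numbers pair the samples was checked from the deviations of arrays from their group means. Same-numbered arrays correlated at 0.277 to 0.462 between PGE2 and control and at 0.228 to 0.529 between TGF-β1 then PGE2 and TGF-β1, but at −0.0472 to 0.296 between TGF-β1 and control and −0.175 to 0.496 between TGF-β1 then PGE2 and control. A replicate block was therefore tried as an alternative, with 1764 higher and 2565 lower genes for PGE2 against control and 2685 and 2712 for TGF-β1 then PGE2 against TGF-β1. In that fit 616 of 18239 genes had an effect of the replicate number at an adjusted p under 0.05. Other alternatives were array weights, a trended and robust variance, cyclic loess, each array minus its median, genes above the median mean, the mean over probe sets, every probe set on its own, a change of at least 1.5-fold, only the groups compared and each array left out in turn. A fit with the 3' minus 5' difference of 2 control transcripts as a covariate was chosen after seeing the data. It is called the RNA quality covariate, although an effect of treatment on those transcripts was not excluded. Because the difference also varied with PGE2, a call lost with the covariate cannot be put down to RNA quality. Reversal counts were set against 100 simulations with shared arrays. The tests were checked on simulated data with 200 of 18239 genes changed. A log2 change of 1 was recovered in 96% of them for TGF-β1 against control, 99% for PGE2 after TGF-β1, 98% for PGE2 against control and 89% for the interaction, and a change of 0.5 in 64%, 65.5%, 73.5% and 6%. Of 24 simulated lists the 1 shifted by 0.5 passed and 0 of the others did in camera. The simulation did not include correlation between the genes of a list. It therefore cannot show whether the list calls hold where such genes are correlated. Of the 41 list calls in the real data, 35 were lost with an estimated correlation.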

Results

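Gene expression was measured with Affymetrix 3' expression arrays in CCL210, a human adult fibroblast line. The cells were given transforming growth factor β1 (TGF-β1), a cytokine that turns fibroblasts into contractile, matrix-producing myofibroblasts, or prostaglandin E2 (PGE2), a lipid mediator that raises cyclic AMP through its EP2 and EP4 receptors. The series asked which transcripts change when TGF-β1 drives this differentiation and when PGE2 reverses it. The 4 groups of 3 arrays were untreated control cells, cells given PGE2 (500 nM for 48 h), cells given TGF-β1 (2 ng/ml for 24 h, then medium for 48 h), and cells given TGF-β1 for 24 h and then PGE2 for 48 h. The labels do not state whether TGF-β1 was also in the later medium. From the deposited log2 values 18239 genes were taken, and the median over genes lay between 6.17 and 6.36 on each of the 12 arrays. Arrays of one group correlated at 0.993 to 0.999 across genes and arrays of different groups at 0.951 to 0.994. The first principal component held 55.1% of the variance and set the 3 TGF-β1 arrays (45.3 to 59.8) apart from the other 9, all below 0. The second held 22.6% and set the 3 control arrays (31.9 to 38.6) apart from the other 9, again all below 0. Changes are log2 fold changes with the standard error of the limma fit, with 3 arrays in each group throughout.

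TGF-β1 raised ACTA2, CNN1, COL1A1 and other genes of the myofibroblast. ACTA2, which encodes smooth muscle α-actin, the usual marker of the myofibroblast, rose by 1.43 ± 0.21 (2.70-fold, adjusted p = 0.00033). TAGLN and CNN1, actin-binding proteins of smooth muscle, rose by 1.06 ± 0.22 and 2.39 ± 0.27, and COL1A1, a chain of type I collagen, rose by 1.01 ± 0.14 (adjusted p = 0.0002). The largest measured rises were those of COMP, a cartilage and tendon matrix protein (6.78 ± 0.45, adjusted p = 1.1e-06), NOX4, an oxidase that makes hydrogen peroxide (6.37 ± 0.30, adjusted p = 8.7e-08), the tetraspanin TSPAN2 (5.77 ± 0.31), cardiac actin ACTC1 (4.77 ± 0.29), PMEPA1, a TGF-β target that restrains SMAD signalling (4.72 ± 0.36), and the Wnt receptor FZD8 (4.60 ± 0.34). Of the 2 ACTC1 probe sets 1 moved the same way. The deepest measured falls were those of ADH1B, an alcohol dehydrogenase (−7.34 ± 0.26, adjusted p = 1e-08), the semaphorin receptor PLXNC1 (−5.23 ± 0.28), the scavenger receptor COLEC12 (−4.71 ± 0.18), the eosinophil chemokine CCL11 (−4.58 ± 1.43), PDE7B, which degrades cyclic AMP (−4.27 ± 0.16), and the glycosyltransferase GALNT15 (−4.21 ± 0.36). Of these 12 genes only FZD8 had both means above 5.79, the 95th percentile of 23 nonspecific control probe sets. The changes of the others may therefore be lower bounds, and their order is open. The CCL11 call (adjusted p = 0.031) rested on arrays that varied widely, since the adjusted p was 0.117 without control array 2, 0.128 without control array 3, 0.0929 without TGF-β1 array 1, 0.0829 without TGF-β1 array 2 and 0.0769 with a trended, robust variance. FN1, fibronectin, rose by 0.27 ± 0.07 (adjusted p = 0.0083), but by 0.99 as the mean of its probe sets (adjusted p = 4.6e-06). The probe set used for FN1 stood at 12.71 in control, and array values reached 13.5. CCN2, a matricellular growth factor, rose by 0.76 ± 0.22 (1.37 as the mean of its probe sets, adjusted p = 0.02, but 0.0816 without control array 1, 0.0572 without TGF-β1 array 1 and 0.0524 without TGF-β1 array 3). COL3A1 rose by 0.20 ± 0.07 (0.39 as the mean of its probe sets, 0.32 with median centring, adjusted p = 0.04), a call that was lost without control array 1 (0.145) or 2 (0.104), without TGF-β1 array 1 (0.124), 2 (0.0711) or 3 (0.0665), and in a fit of these 6 arrays alone (0.111). POSTN, periostin, had a change of 0.58 ± 0.41 (adjusted p = 0.38). TGFB1 itself rose by 1.76 ± 0.13. PTGS2, the inducible cyclooxygenase, had a change of 1.10 ± 0.51 that did not pass (adjusted p = 0.14, 0.0397 in a fit of these 6 arrays alone), while the PGE2 receptor genes PTGER2 and PTGER4 fell, by −1.56 ± 0.13 and −1.46 ± 0.35 (−0.82 as the mean of the PTGER4 probe sets).

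The gene lists fixed in advance gave the same comparison by group. Of 22 contractile and cytoskeletal genes, 14 rose with TGF-β1, among them MYH11 (2.59), TNS1 (2.38) and ACTG2 (2.23), VCL fell (−0.36) and 7 did not pass (14 higher and 1 lower adjusted over the list alone). Contractile genes had a camera adjusted p of 3.3e-07, adjusted p = 0.21 with an estimated correlation. Of 21 collagens, 14 rose, including COL11A1 (3.98) and, as possible lower bounds, COL15A1 (4.48 ± 0.37) and COL10A1 (3.65). Of the others 5 fell, COL14A1 the furthest (−2.97), and the counts were 14 and 5 adjusted over the list alone. Collagens had an adjusted p of 8.3e-06, 0.21 as the adjusted p with an estimated correlation. Matrix glycoproteins, proteoglycans and elastic fibre genes rose in 12 of 24, including elastin ELN (3.82) and the microfibril protein MFAP5 (3.45), and fell in 3, including FBLN1 (−2.89), or 17 and 3 adjusted over the list alone. Matrix glycoproteins had an adjusted p of 1.6e-06, and adjusted p = 0.21 with an estimated correlation. Collagen processing and cross-linking enzymes rose in 12 of 19, such as the lysyl hydroxylase PLOD2 (1.70) and LOXL2 (1.32), and fell in 3, such as PCOLCE (−0.96), or 15 and 3 adjusted over the list alone. Collagen processing enzymes had an adjusted p of 3.1e-05, and adjusted p = 0.21 with an estimated correlation. Of 21 TGF-β targets and feedback genes, 14 rose, including IL11 (3.51), IGFBP3 (2.88), NOX4 and PMEPA1, and 3 fell, which were SMAD3 (−2.40), SMAD6 (−0.88) and BAMBI (−0.60), and the counts were equal adjusted over the list alone (adjusted p = 7.4e-07, and adjusted p = 0.15 with an estimated correlation).

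The amino acid synthesis and unfolded protein response lists also passed camera upward with TGF-β1, but not with an estimated correlation (adjusted p = 0.15 and 0.068). Of 15 genes listed for serine, glycine, proline and asparagine synthesis and related steps, 13 rose and none fell, including CHAC1, which degrades glutathione (1.86 ± 0.18), the transporter SLC7A5 (1.75), and PSPH (1.57) and PSAT1 (1.22) of the serine pathway (13 and 0 adjusted over the list alone). Amino acid genes had an adjusted p of 2.5e-09, and adjusted p = 0.15 with an estimated correlation. Of 20 unfolded protein response genes, 11 rose, including TRIB3 (1.60 ± 0.14), XBP1 (1.00) and DNAJB11 (0.71), and CRELD2 fell (−0.47), or 14 and 1 adjusted over the list alone. Unfolded protein response genes had an adjusted p of 1.2e-06, and adjusted p = 0.068 with an estimated correlation. Genes that respond to cyclic AMP fell in 9 of 23, including PDE4B (−2.78) and RGS2 (−2.69), and rose in 3, including SIK1 (3.31), with 9 and 4 adjusted over the list alone. Their camera adjusted p of 0.048 (adjusted p = 0.21 with an estimated correlation) became 0.0824 without control array 2 and 0.0552 without TGF-β1 array 2. Lipid storage and lipofibroblast genes fell in 8 of 19, including the mesenchymal transcription factor TCF21 (−3.52 ± 0.12), the adipogenic receptor PPARG (−1.92) and the lipid droplet protein PLIN2 (−1.12), and rose in 2, including ACSL1 (0.61) (1 without control array 2 or 3 or TGF-β1 array 1), with 9 and 2 adjusted over the list alone. For lipid storage genes the adjusted p of 0.035 (adjusted p = 0.23 with an estimated correlation) became 0.0829 without control array 1, 0.0632 without TGF-β1 array 3 and 0.0536 with RNA quality as a covariate.

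Other lists moved in both directions or in few members and did not pass camera between TGF-β1 and control. Of 18 genes of prostaglandin synthesis, transport and reception, 7 fell, including the PGE2 synthase PTGES (−2.14) and PTGFR (−1.53), and 3 rose, including PTGS1 (0.62), or 8 and 3 adjusted over the list alone. Prostaglandin genes had an adjusted p of 0.076, 5.1e-05 with fry, 0.0455 without TGF-β1 array 2 and 0.0119 with median centring. Of 23 integrins and adhesion genes, 9 rose, including the collagen receptors ITGA1 (3.09) and ITGA11 (2.82), and ITGB8 (−3.43), VCAM1 (−2.58) and CD44 (−0.40) fell (5 fell without control array 2), or 10 and 3 adjusted over the list alone. Integrins and adhesion genes had an adjusted p of 0.052, 0.00664 with fry, 0.0271 without control array 1, 0.0407 without TGF-β1 array 3 and 0.0322 with RNA quality as a covariate. Hyaluronan and growth factor genes rose in 9 of 21, including IGF1 (4.13) and HBEGF (4.11), and fell in 3, including FGF7 (−1.93), or 9 and 3 adjusted over the list alone. Growth factor genes had an adjusted p of 0.057, 0.00664 with fry, 0.0364 without control array 1, 0.0407 without TGF-β1 array 3 and 0.0376 with RNA quality as a covariate. Among 22 cytokines and chemokines, CCL2 (−4.13), CXCL12 (−2.56) and IL33 (−2.25) fell with CCL11, and 3 rose, including LIF (2.19) and IL6 (1.64), or 4 lower and 3 higher adjusted over the list alone. Cytokines and chemokines had an adjusted p of 0.79, 0.0105 with fry. Of 21 metalloproteinase and plasminogen system genes 6 rose and 5 fell, by either adjustment, with ADAM12 up (2.95) and ADAMTS1 down (−1.80) (list adjusted p = 0.52). Of 25 Wnt pathway genes 4 rose and 6 fell, by either adjustment, with SFRP1, a secreted Wnt inhibitor, down by −2.72 ± 0.09 (list adjusted p = 0.6). Of 19 oxidative stress genes 3 rose and 7 fell, by either adjustment, including GPX3 (−2.84) and SOD3 (−1.80) (list adjusted p = 0.31, 0.00664 with fry). Interferon-stimulated genes fell in 3 of 21, by either adjustment, which were IFIT1 (−2.34), IFIH1 (−1.99) and IFIT3 (−1.71) (list adjusted p = 0.33, but 0.0242 without TGF-β1 array 2, when 8 fell). Of 28 cell cycle genes CCNA2 rose (1.83) and 5 fell, TYMS the furthest (−0.98) (3 without control array 3 or TGF-β1 array 2), or 1 and 4 adjusted over the list alone. Cell cycle genes had an adjusted p of 0.6. Of 17 cholesterol synthesis genes 3 rose and LSS fell (−1.37), by either adjustment (list adjusted p = 0.6, 0.0174 without control array 1). For cholesterol synthesis 5 rose without control array 1 and 1 without control array 2 or 3, and 2 fell without control array 3 or TGF-β1 array 2. Of 20 apoptosis and survival genes 5 rose, TNFRSF10D the furthest (1.37), and 4 fell, or 6 and 4 adjusted over the list alone. Apoptosis genes had an adjusted p of 0.76.

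Markers of other cell types did not pass camera between TGF-β1 and control. Of 12 epithelial markers, KRT7 (4.27 ± 0.37) and KRT18 (3.13 ± 0.34) rose and the other 10 did not pass (adjusted p = 0.25, but 0.0225 with fry). No member of the 11 endothelial markers passed (adjusted p = 0.6), CD68 (−1.52) fell among 12 leukocyte markers (adjusted p = 0.93), and of 9 pericyte markers MCAM (1.02) and NOTCH3 (0.56) rose while ABCC9 (−1.79) and ANPEP (−1.30) fell (adjusted p = 1). The counts of these 4 lists were equal adjusted over the list alone. In all, 2127 genes were higher and 2968 lower in TGF-β1 than in control, 390 and 610 of them by at least 2-fold. The higher share of 41.7% became 63.0% when each array was centred on its median, with 3628 genes higher.

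**Figure D1:**
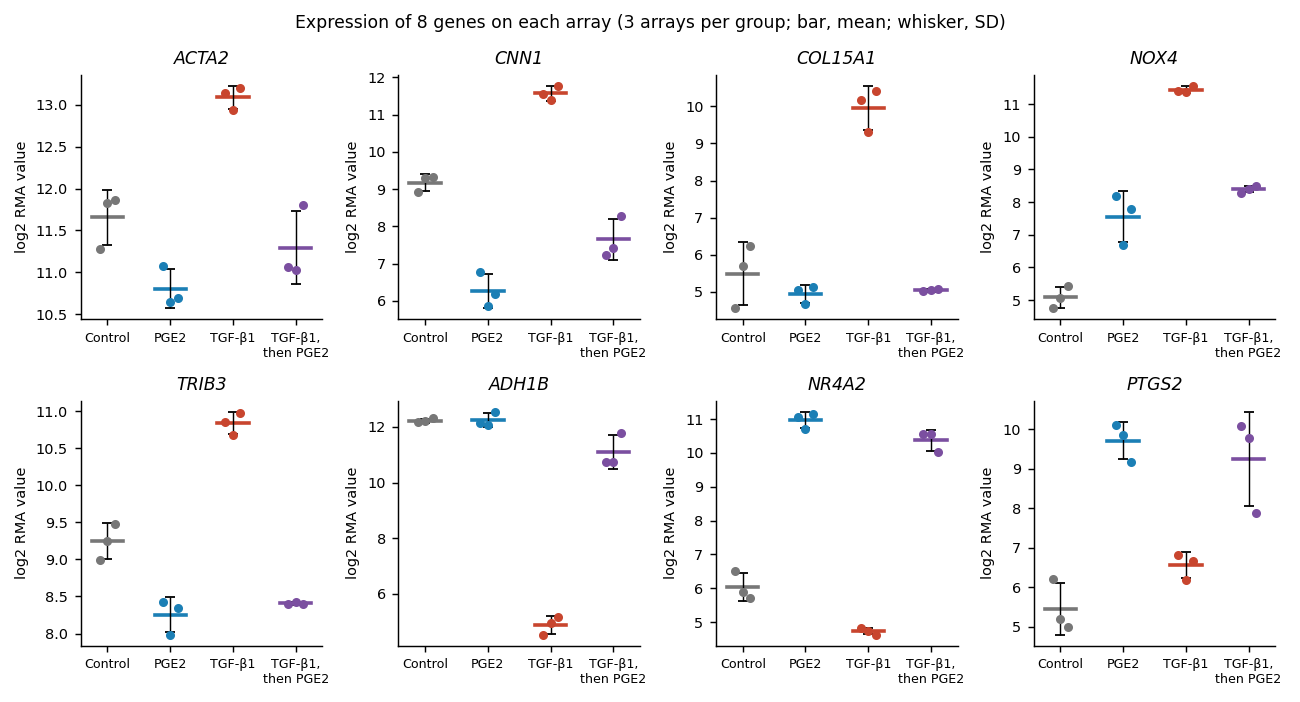
Log2 expression of 8 genes on each of the 12 arrays, with group on the horizontal axis and the deposited log2 value on the vertical axis; points are arrays, bars are means of 3 arrays and whiskers are SD. ACTA2 and CNN1 stand highest in TGF-β1 (13.09 and 11.57) and near or under control after PGE2 followed (11.29 and 7.65), ADH1B falls from 12.23 to 4.89 with TGF-β1 and stands at 11.09 after PGE2, and NR4A2 and PTGS2 stand highest in the 2 groups with PGE2.

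PGE2 given after TGF-β1 lowered ACTA2, TAGLN, CNN1 and COL1A1 and raised PTGS2 and NR4A2. Against TGF-β1 alone, ACTA2 fell by −1.80 ± 0.21 (3.47-fold, adjusted p = 7.1e-05), TAGLN by −1.61 ± 0.22, CNN1 by −3.92 ± 0.27 (15.2-fold, adjusted p = 1.3e-06) and COL1A1 by −0.77 ± 0.14 (adjusted p = 0.0015). The deepest measured falls besides CNN1 were those of the basement membrane collagen COL15A1 (−4.93 ± 0.37, adjusted p = 2.2e-06), TNFSF4, the OX40 ligand (−4.52 ± 0.19), RTKN2 (−3.92 ± 0.57), the bone morphogenetic protein family member GDF6 (−3.90 ± 0.19) and ACTC1 (−3.90 ± 0.29). The largest measured rises were those of ADH1B (6.21 ± 0.26), the endothelin receptor EDNRB (6.11 ± 0.29), PDE7B (5.76 ± 0.16), the early response nuclear receptor NR4A2 (5.65 ± 0.20, adjusted p = 1.2e-08), the Notch ligand DNER (4.48 ± 0.14) and the tetraspanin TSPAN12 (4.39 ± 0.18). Among these 12 genes only CNN1 and TNFSF4 had both means above the level of the nonspecific controls (5.79). The other changes may therefore be lower bounds, and their order is open. TGFB1 fell by −1.15 ± 0.13, PTGS2 rose by 2.69 ± 0.51 (adjusted p = 0.002), and PTGER2 and PTGER4 rose by 1.42 ± 0.13 and 1.69 ± 0.35 (0.97 as the mean of the PTGER4 probe sets). COL3A1 (0.05 ± 0.07, adjusted p = 0.65) and CCN2 (−0.27 ± 0.22, adjusted p = 0.45, 0.0215 in a fit of these 6 arrays alone) did not pass. FN1 did not pass either (−0.07 ± 0.07, adjusted p = 0.52), but the mean of its probe sets did (−0.47, adjusted p = 0.0012). POSTN had a change of −0.95 ± 0.41 (adjusted p = 0.13) that passed with the replicate block (adjusted p = 0.0343), with array weights (0.0315) and in a fit of these 6 arrays alone (0.0152). Arrays with PGE2 also differed in a possible sign of RNA quality, the difference between 3' and 5' probe sets of the control transcripts. It was 0.968 ± 0.215 (SD, n = 3) after TGF-β1 and PGE2 against 0.626 ± 0.223 after TGF-β1. With PGE2 alone it was 1.22 ± 0.312 against 0.818 ± 0.157 in control. Over all 12 arrays those with PGE2 lay 0.374 higher (exact permutation p = 0.02, two-sided, 400 permutations within TGF-β1 levels). The permutation did not keep same-numbered arrays together. PGE2 array 3 (0.995) did not lie above control array 3 (0.999), while the other same-numbered arrays with PGE2 lay higher. Whether the 3' minus 5' difference reflects RNA quality or an effect of PGE2 on those transcripts was not settled. Within groups 0 genes followed it at an adjusted p under 0.05 in the limma fit, but 2805 did at an unadjusted p under 0.05. The count of 0 therefore does not show that expression was unrelated to that difference. With that difference as a covariate, chosen after seeing the data, none of the genes named in this paragraph with a call lost it.

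By list, PGE2 after TGF-β1 lowered 19 of 22 contractile genes, including ACTG2 (−3.80), MYH11 (−2.77) and TNS1 (−2.11), and raised MYOCD (1.19), the cofactor that drives smooth muscle genes, or 21 and 1 adjusted over the list alone. Contractile genes had a camera adjusted p of 1.1e-11, and adjusted p = 0.17 with an estimated correlation. Collagen processing enzymes fell in 13 of 19, including LOXL4 (−1.45) and LOX (−1.25), while P4HA3 (3.02) and PCOLCE (0.81) rose, or 13 and 3 adjusted over the list alone. Collagen processing enzymes had an adjusted p of 0.00084, and adjusted p = 0.23 with an estimated correlation. Integrins and adhesion genes fell in 12 of 23, including ITGA11 (−2.48), ITGA1 (−2.27) and N-cadherin CDH2 (−1.70), while 2 rose, ITGB8 the further (1.63) (1 without TGF-β1 array 1 or 3 or arrays 1 or 2 of TGF-β1 then PGE2), or 12 and 4 adjusted over the list alone. Integrins and adhesion genes had an adjusted p of 0.0011, and adjusted p = 0.17 with an estimated correlation. Genes of the amino acid list fell in 11 of 15, by either adjustment, and none rose, including CHAC1 (−2.13), PSAT1 (−1.96), ASNS (−1.94) and PHGDH (−1.83) (adjusted p = 6.4e-07, and adjusted p = 0.17 with an estimated correlation). Unfolded protein response genes fell in 8 of 20, including TRIB3 (−2.43), DDIT3 (−1.18) and XBP1 (−0.76, or −0.50 with the RNA quality covariate), and CRELD2 rose (0.47), or 9 and 4 adjusted over the list alone. The unfolded protein response list had an adjusted p of 0.012, and adjusted p = 0.17 with an estimated correlation.

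Among the lists that passed camera upward with PGE2 after TGF-β1, genes that respond to cyclic AMP rose in 14 of 23, including RGS2 (4.35 ± 0.31) and PDE4B, while CREB3L1 (−1.67) and ATF3 (−1.11) fell, or 16 and 2 adjusted over the list alone. Cyclic AMP genes had an adjusted p of 2.7e-08, and adjusted p = 0.018 with an estimated correlation. Prostaglandin genes rose in 10 of 18, including PTGES (2.67) and AKR1C3 (1.75), and 1 fell (2 without TGF-β1 array 3), or 10 and 2 adjusted over the list alone. Prostaglandin genes had an adjusted p of 0.0011, and adjusted p = 0.082 with an estimated correlation. Cytokines and chemokines rose in 10 of 22, including CCL2 (4.28), CXCL6 (3.16), IL33 (3.02) and CCL7 (3.01), while 2 fell, including IL6 (−1.46) (1 without TGF-β1 array 1 or 2 or array 3 of TGF-β1 then PGE2), or 11 and 2 adjusted over the list alone. Cytokines and chemokines had an adjusted p of 0.0046, and adjusted p = 0.17 with an estimated correlation. Oxidative stress genes rose in 7 of 19, including catalase CAT (1.56), and GCLM fell, by either adjustment. For oxidative stress genes the adjusted p of 0.012 (adjusted p = 0.44 with an estimated correlation) became 0.0889 without TGF-β1 array 3, when 4 rose, and 0.0973 with the RNA quality covariate, with which 3 rose. Lipid storage genes rose in 5 of 19, including TCF21 (3.39) and CEBPD (1.37), while 2 fell (1 without TGF-β1 array 1 or array 3 of TGF-β1 then PGE2), with 6 and 2 adjusted over the list alone. For lipid storage genes the adjusted p of 0.029 (adjusted p = 0.29 with an estimated correlation) became 0.0838 without TGF-β1 array 3 and 0.0603 with the RNA quality covariate.

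Several lists did not pass camera with PGE2 after TGF-β1. Of 21 collagens 9 fell, including COL8A2 (−3.27) and COL11A1 (−2.39), and COL14A1 and COL18A1 (1.36) rose, or 10 and 3 adjusted over the list alone. Collagens had an adjusted p of 0.055, but 0.00585 with fry, 0.0383 without TGF-β1 array 3, and 0.0363 and 0.0444 without arrays 1 and 3 of TGF-β1 then PGE2. The same list passed with cyclic loess (0.0182) and with the RNA quality covariate (0.0238). TGF-β targets fell in 8 of 21, including NOX4 (−3.06), SKIL (−1.78) and BHLHE40 (−1.57), and 3 rose, including ID3 (1.66) and SMAD3 (0.79), with 10 and 5 adjusted over the list alone. Their adjusted p was 0.055, and it was 0.00559 with fry, 0.0462 with the replicate block, 0.0363 without array 1 of TGF-β1 then PGE2, 0.0339 with cyclic loess and 0.0125 with the RNA quality covariate. Matrix glycoproteins fell in 8 of 24, including MFAP5 (−2.78), ASPN (−2.68) and ELN (−2.31), and rose in 4, or 8 and 5 adjusted over the list alone. Matrix glycoproteins had an adjusted p of 0.23. Metalloproteinase system genes rose in 8 of 21, including MMP10 (3.40) and the plasminogen activator PLAT (2.48), and fell in 4, including ADAM12 (−2.81), or 9 and 4 adjusted over the list alone. Metalloproteinase system genes had an adjusted p of 0.28, 0.0125 with fry. Wnt pathway genes rose in 6 of 25, including SFRP1 (2.88) and RSPO3 (2.68), and fell in 4, including FZD8 (−2.25), or 7 and 4 adjusted over the list alone. Wnt pathway genes had an adjusted p of 0.39, 0.017 with fry. Growth factor genes rose in 6 of 21, including STC1 (4.27) and EREG (4.27), and fell in 6, including HBEGF (−3.56), or 7 each way adjusted over the list alone. Growth factor genes had an adjusted p of 0.47, 0.00318 with fry. KRT7 (−3.21) and KRT18 (−3.12) fell among 12 epithelial markers (adjusted p = 0.1, 0.0469 without TGF-β1 array 1 and 0.00542 with fry), and CD68 rose (1.34, a call lost without TGF-β1 array 3 and without arrays 1 or 2 of TGF-β1 then PGE2, with an adjusted p of up to 0.084 without array 1) among leukocyte markers, a list with an adjusted p of 0.92.

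In all, 2230 genes were higher and 2205 lower after TGF-β1 and PGE2 than after TGF-β1 alone, 560 and 383 of them by at least 2-fold, and the higher share of 50.3% became 39.2% with median centring. Of the 2127 genes that TGF-β1 raised, PGE2 then lowered 1416 (66.6%), raised 35 further and left 676 without a call. ACTA2, CNN1, COL1A1 and NOX4 were among the 1416. Of the 2968 genes that TGF-β1 lowered, PGE2 raised 1624 (54.7%), including ADH1B, PDE7B and TCF21, lowered 41 further and left 1303 without a call. Both comparisons share the TGF-β1 arrays. Arrays simulated with no PGE2 effect gave a mean of 5.37 genes raised then lowered (highest 298 of 100 simulations) and 8.63 lowered then raised (highest 590), and independent lists would share 257 and 363. The 3 TGF-β1 arrays could not be split into parts of at least 2, so part of the excess may come from sharing them. Across genes the changes with TGF-β1 and with PGE2 after it correlated at −0.744 against −0.477 in simulations without any treatment effect, with a covariance of −0.204 against −0.00903, a difference of −0.195. Genes are not independent replicates in these correlations. Counted against control, 1151 of the 1416 no longer differed in the test, 123 were still higher and 142 were lower, and of the 1624, 1205 had no call, 257 were still lower and 162 were higher. With PGE2 alone 324 of the 1416 also fell, such as CNN1 and COL1A1, and 134 rose, such as NOX4. Of the 1624, 311 also rose with PGE2 alone and 267 fell. The interaction was called lower for 792 of the 1416 and higher for 1027 of the 1624.

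A measure free of shared arrays set the TGF-β1 effect among PGE2-treated cells, TGF-β1 then PGE2 minus PGE2, against the effect among cells without PGE2. Over the 5095 genes called with TGF-β1 the slope was 0.17 (SD 0.0386 over the 3 replicate numbers), 0.30 for raised and 0.13 for lowered genes. Simulated additive effects gave a mean slope of 0.941 and a lowest of 0.685.

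**Figure D2:**
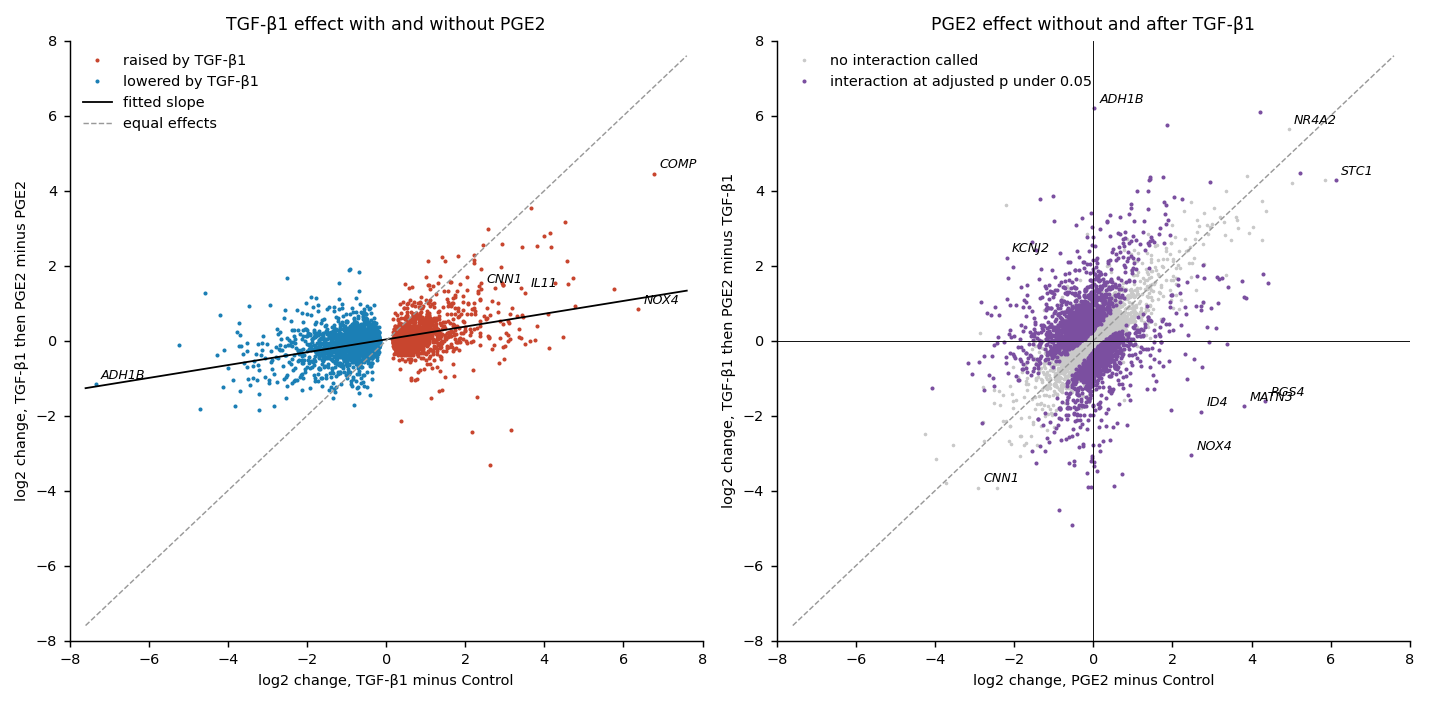
The left panel plots the log2 change with TGF-β1 in PGE2-treated cells against that without PGE2 for the 5095 genes called with TGF-β1, with the line of equal effects and the fitted slope of 0.17; the right panel plots the log2 change with PGE2 after TGF-β1 against that of PGE2 alone, with the genes called for the interaction in purple (1783 above and 1231 below). Each point is a gene and a difference between means of 3 arrays.

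PGE2 alone, in cells never given TGF-β1, lowered CNN1, TAGLN and COL1A1 and raised STC1, EREG, NR4A2 and PTGS2. Against control, CNN1 fell by −2.91 ± 0.27 (7.52-fold, adjusted p = 2.2e-05, −1.68 as the mean of its probe sets), TAGLN by −2.02 ± 0.22 and COL1A1 by −0.85 ± 0.14 (adjusted p = 0.0012). ACTA2 fell by −0.85 ± 0.21 (adjusted p = 0.015), a call that was lost without control array 2 (0.0596) or 3 (0.0603), without PGE2 array 2 (0.0595) or 3 (0.0506), with the RNA quality covariate (0.0777) and for the mean of its probe sets (−0.53, adjusted p = 0.0534). The largest measured rises were those of STC1, the secreted hormone stanniocalcin (6.13 ± 0.39, 70.1-fold, adjusted p = 1.7e-06), EREG, an EGF receptor ligand (5.87 ± 0.41), DNER (5.22 ± 0.14), KYNU of the kynurenine pathway (5.02 ± 0.42), NR4A2 (4.94 ± 0.20) and PDK4, which inhibits pyruvate dehydrogenase (4.41 ± 0.47). The deepest measured falls were those of the oxytocin receptor OXTR (−4.26 ± 0.48, adjusted p = 8.3e-05), DEPP1 (−4.09 ± 0.26), MAP3K7CL (−3.97 ± 0.19), the smooth muscle actin ACTG2 (−3.73 ± 0.33), the scavenger receptor OLR1 (−3.54 ± 0.50) and IRAG1 (−3.17 ± 0.12). EREG, KYNU, PDK4, OXTR, DEPP1 and OLR1 had a mean under the 95th percentile of the nonspecific controls (5.79) in 1 group. Their changes may therefore be lower bounds, and their order is open. PTGS2, at 5.46 in control, rose by 4.26 ± 0.51 (adjusted p = 0.00012) and TGFB1 by 0.65 ± 0.13 (adjusted p = 0.0035). POSTN (−0.68 ± 0.41, adjusted p = 0.33), COL3A1 (0.07 ± 0.07, adjusted p = 0.61) and CCN2 (−0.25 ± 0.22, adjusted p = 0.53) did not pass. FN1 had a change of −0.14 ± 0.07 (adjusted p = 0.21), but passed as the mean of its probe sets (−0.42, adjusted p = 0.0032) and with the RNA quality covariate (−0.23, adjusted p = 0.0459). PTGER2 had a change of −0.03 ± 0.13 (adjusted p = 0.93), which was −0.32 with that covariate (adjusted p = 0.0494), and PTGER4 one of 0.61 ± 0.35 (adjusted p = 0.3), which was 1.03 without control array 3 (adjusted p = 0.0436).

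By list, 16 of 22 contractile genes fell with PGE2 alone, including ACTG2, SYNPO2 (−3.07), CNN1 and TAGLN, and 1 rose, or 17 and 1 adjusted over the list alone. Contractile genes had a camera adjusted p of 6.2e-10, and adjusted p = 0.13 with an estimated correlation. Unfolded protein response genes rose in 14 of 20, including the endoplasmic reticulum chaperone CALR (1.25 ± 0.14) and MANF (0.84 ± 0.06), while TRIB3 (−0.99) and DDIT3 (−0.80), which mark the PERK and ATF4 branch, fell, or 15 and 3 adjusted over the list alone. Unfolded protein response genes had an adjusted p of 4.7e-08, and adjusted p = 0.016 with an estimated correlation. Genes that respond to cyclic AMP rose in 14 of 23, including SIK1 (3.81) and PPARGC1A (3.20), while 3 fell, including CREB3L1 (−1.32) and CITED2 (−0.74), or 14 and 5 adjusted over the list alone. Cyclic AMP genes had an adjusted p of 1.9e-07, and adjusted p = 0.016 with an estimated correlation. Hyaluronan and growth factor genes rose in 8 of 21, including HGF, and fell in 3, including STC2 (−1.96), or 10 and 5 adjusted over the list alone. Growth factor genes had an adjusted p of 0.0028, and adjusted p = 0.11 with an estimated correlation. Metalloproteinase system genes rose in 5 of 21, including MMP10 (2.79), PLAT (1.84) and PLAUR (1.65), and 2 fell, including ADAM12 (−1.35) (1 without control array 1 or 3), or 7 and 2 adjusted over the list alone. Metalloproteinase system genes had an adjusted p of 0.0028, and adjusted p = 0.11 with an estimated correlation. Cytokines and chemokines rose in 7 of 22, including CCL7 (3.65), CXCL6 (3.30, or 2.17 with the RNA quality covariate) and LIF (2.93), and CSF1 fell (−0.31, a call lost when any 1 of 4 arrays was left out, with an adjusted p of up to 0.107 without PGE2 array 1), or 9 and 1 adjusted over the list alone. Cytokines and chemokines had an adjusted p of 0.005, and adjusted p = 0.11 with an estimated correlation. Prostaglandin genes rose in 5 of 18, including PTGS1 (1.46) and PTGES (1.44), and PTGIS fell (−0.89, a call lost without control array 2 or 3 or PGE2 array 1 or 2, with an adjusted p of up to 0.0715 without PGE2 array 1), with 6 and 1 adjusted over the list alone. For prostaglandin genes the adjusted p of 0.023 (adjusted p = 0.11 with an estimated correlation) became 0.128 with the RNA quality covariate.

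Among the lists that did not pass camera with PGE2 alone, 8 of 21 TGF-β targets rose, including ID1 (3.87 ± 0.32), ID3 (3.17), PMEPA1 (2.55) and NOX4 (2.47), and 5 fell, or 8 and 6 adjusted over the list alone. TGF-β targets had an adjusted p of 0.18. Matrix glycoproteins fell in 7 of 24, including tenascin TNC (−2.78) and ASPN (−2.77), and VCAN (1.69), LTBP1 (0.60) and MFAP4 (0.40) rose, by either adjustment (adjusted p = 0.11, but 0.0165 without control array 1, 0.0428 without PGE2 array 1, 0.0427 with cyclic loess and 0.0343 with median centring). Integrins and adhesion genes fell in 9 of 23, including VCAM1 (−2.54) and ITGA3 (−1.11), and rose in 4 (2 without control array 2 or PGE2 array 1), or 11 and 4 adjusted over the list alone. Integrins and adhesion genes had an adjusted p of 0.085, but 0.000703 with fry, 0.0215 without PGE2 array 1, 0.0491 with cyclic loess, 0.0376 with median centring and 0.0169 with the RNA quality covariate. Of 21 collagens 7 fell and 3 rose, including COL8A2 (−1.45) and COL18A1 (1.34), or 8 and 5 adjusted over the list alone. Collagens had an adjusted p of 0.93. Of 15 genes of the amino acid list 7 fell, including PHGDH (−1.29) and MTHFD2 (−1.10) (4 without control array 2 or 3 or PGE2 array 2), and 2 rose, SLC7A5 the further (1.65) (1 without PGE2 array 1), or 8 and 4 adjusted over the list alone. Amino acid genes had an adjusted p of 0.26. RGS5 (2.88) and KCNJ8 (1.37) rose and CSPG4 (−0.92) fell among 9 pericyte markers, by either adjustment (adjusted p = 0.066, 0.0499 without PGE2 array 2 and 0.000161 with fry). Of the epithelial markers KRT19 fell (−1.24, a call lost without PGE2 array 1, 2 or 3, with an adjusted p of up to 0.0809 without array 3; none fell adjusted over the list alone), and no endothelial or leukocyte marker passed. In all, 1431 genes were higher and 2045 lower with PGE2 alone, 327 and 332 of them by at least 2-fold. The higher share of 41.2% became 53.7% with median centring, and 888 genes were higher with the RNA quality covariate. PGE2 raised 650 genes and lowered 738 in both settings, with and without TGF-β1, against 175 and 247 for independent lists.

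**Figure D3:**
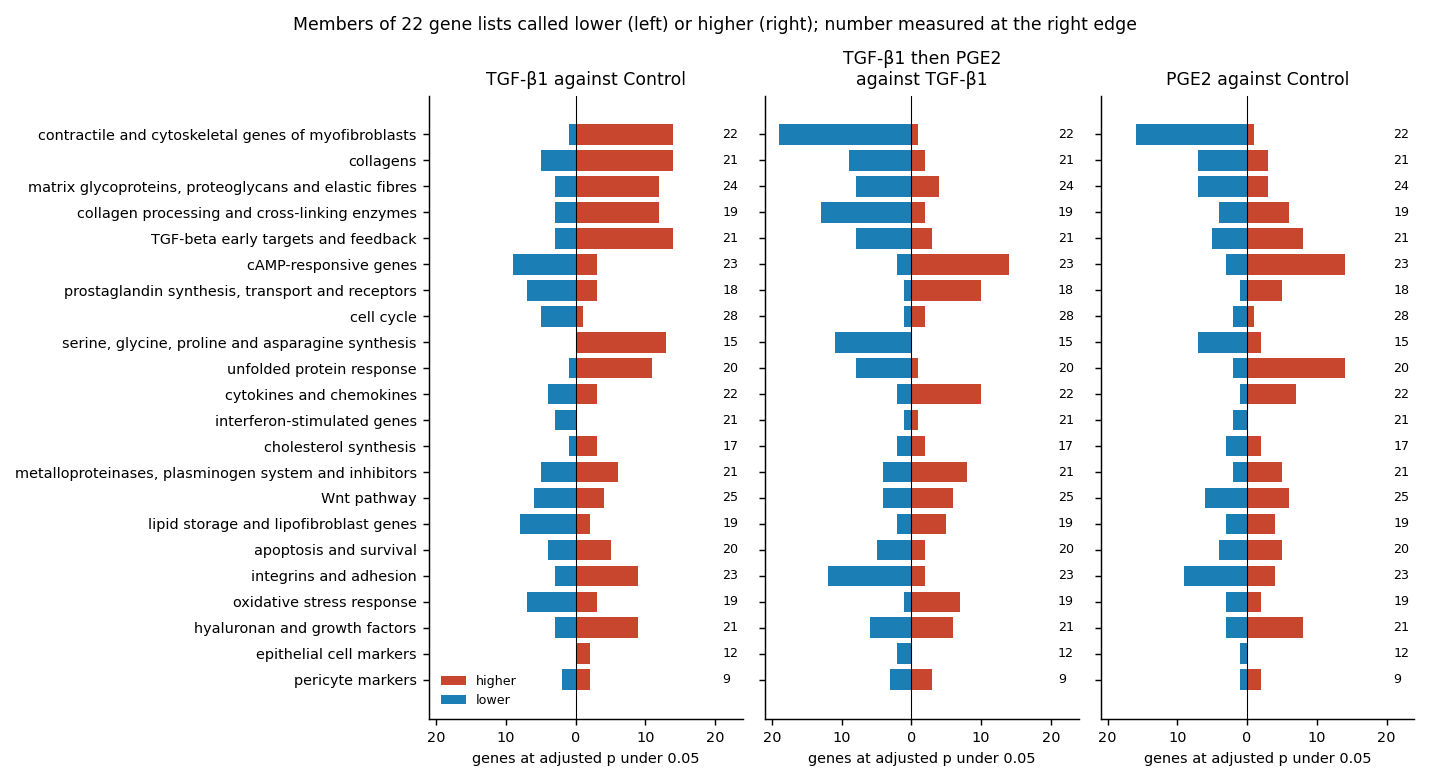
Number of members of 22 gene lists past the threshold, higher to the right and lower to the left of 0, in 3 comparisons of 3 against 3 arrays; the number at the right edge is the measured members. Contractile genes stand to the right with TGF-β1 (14 of 22) and to the left with PGE2 after TGF-β1 (19) and PGE2 alone (16), while unfolded protein response genes stand to the right with TGF-β1 (11 of 20) and PGE2 alone (14) and to the left with PGE2 after TGF-β1 (8).

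Cells given both treatments still differed from control in part of their genes. ACTA2 (−0.36 ± 0.21, adjusted p = 0.33) and TAGLN (−0.55 ± 0.22, adjusted p = 0.14) did not differ from control in the test, but were lower without array 3 of TGF-β1 then PGE2 (−0.62, adjusted p = 0.0434, and −0.77, adjusted p = 0.0299) and with array weights (−0.56, adjusted p = 0.043, and −0.69, adjusted p = 0.019). CNN1 was lower by −1.53 ± 0.27 (adjusted p = 0.0031). The genes measured furthest above control were the neutrophil chemokine CXCL6 (5.38 ± 0.57, adjusted p = 9.9e-05), COMP (5.33 ± 0.45), EREG (5.00 ± 0.41), STC1 (4.75 ± 0.39), the lubricating proteoglycan PRG4 (4.60 ± 0.81) and FNDC1 (4.54 ± 0.18). Those measured furthest below were the adhesion molecule VCAM1 (−3.57 ± 0.21, 11.9-fold, adjusted p = 1.1e-06), the protease inhibitor A2M (−2.92 ± 0.26), IGSF10 (−2.90 ± 0.11), the guanylate cyclase subunit GUCY1A1 (−2.86 ± 0.29), FMO2 (−2.84 ± 0.44) and CLEC3B (−2.71 ± 0.23). Because 1 mean lay under the 95th percentile of the nonspecific controls (5.79), as for CXCL6 at 3.95, EREG at 3.92 and PRG4 at 3.87 in control, the changes of CXCL6, COMP, EREG, PRG4, FNDC1, IGSF10, GUCY1A1 and FMO2 are lower bounds without an order. COL1A1 (0.23 ± 0.14, adjusted p = 0.35), POSTN (−0.37 ± 0.41, adjusted p = 0.66), CCN2 (0.49 ± 0.22, adjusted p = 0.18), PTGER2 (−0.13 ± 0.13, adjusted p = 0.62) and PTGER4 (0.23 ± 0.35, adjusted p = 0.77) did not pass. PTGER4 turned to −0.28 without control array 1. FN1 had a change of 0.20 ± 0.07 (adjusted p = 0.069) and passed as the mean of its probe sets (0.53, adjusted p = 0.0013), with array weights (0.0129), with median centring (0.0189), among brighter genes (0.0446) and with a trended, robust variance (0.023). COL3A1 was higher by 0.25 ± 0.07 (0.41 as the mean of its probe sets, adjusted p = 0.023), a call lost without control array 1 (0.0826) or 2 (0.0702), without arrays 1 (0.0758) or 2 (0.0788) of TGF-β1 then PGE2, and in a fit of these 6 arrays alone (0.0589). TGFB1 was higher by 0.61 ± 0.13 and PTGS2 by 3.79 ± 0.51.

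By list, after both treatments, cyclic AMP genes were higher than control in 12 of 23, including SIK1 (4.48) and NR4A2 (4.34), and lower in 4, or 14 and 5 adjusted over the list alone. Cyclic AMP genes had a camera adjusted p of 2.4e-08, and adjusted p = 0.016 with an estimated correlation. Growth factor genes were higher in 8 of 21, including IGF1 (3.42) and HGF (1.78), and lower in 2, including STC2 (−1.60) (1 without control array 2 or 3 or arrays 1 or 2 of TGF-β1 then PGE2), or 10 and 2 adjusted over the list alone. Growth factor genes had an adjusted p of 2.3e-06, and adjusted p = 0.022 with an estimated correlation. TGF-β targets were higher in 8 of 21, including PMEPA1 (4.21), IL11 (3.66) and NOX4 (3.31), and lower in 2, including SMAD3 (−1.61) (4 without control array 1, and 1 without control array 2 or 3 or arrays 1 or 2 of TGF-β1 then PGE2), or 10 and 4 adjusted over the list alone. TGF-β targets had an adjusted p of 3.1e-05, and adjusted p = 0.18 with an estimated correlation. Matrix glycoproteins were higher in 6 of 24, including VCAN (1.90), and TNC was lower (−1.53; 2 were lower without array 3 of TGF-β1 then PGE2), or 9 and 1 adjusted over the list alone. Matrix glycoproteins had an adjusted p of 1.4e-05, and adjusted p = 0.24 with an estimated correlation. Collagens were higher in 8 of 21, including COL10A1 (4.08), COL11A1 (1.60) and COL4A1, and COL6A2 (−0.67) and COL6A1 (−0.32) were lower, or 9 and 3 adjusted over the list alone. Collagens had an adjusted p of 0.00074, and adjusted p = 0.42 with an estimated correlation. Metalloproteinase system genes were higher in 7 of 21, including MMP10 (3.55), and lower in 2, including PLAU (−0.80), or 8 and 3 adjusted over the list alone. The count of higher genes was 3 without array 1 of TGF-β1 then PGE2 and 4 without array 2 of that group, and 1 gene was lower without control array 1 or 3 or any 1 array of TGF-β1 then PGE2. Metalloproteinase system genes had an adjusted p of 0.00074, and adjusted p = 0.11 with an estimated correlation. Cytokines were higher in 8 of 22, including CXCL8 (2.99) and CXCL3 (2.35), and lower in 2, including CXCL12 (−0.61) (1 without arrays 1 or 2 of TGF-β1 then PGE2), or 9 and 3 adjusted over the list alone. Cytokines and chemokines had an adjusted p of 0.0012, and adjusted p = 0.11 with an estimated correlation. Contractile genes were lower in 10 of 22, including LMOD1 (−1.66) and ACTG2 (−1.57), and MYOCD was higher (1.99), by either adjustment (adjusted p = 0.0029, and adjusted p = 0.6 with an estimated correlation). Unfolded protein response genes were higher in 5 of 20, including DNAJC3 (0.49), and TRIB3 (−0.83) and DDIT3 (−0.65) were lower, by either adjustment. That count of higher genes was 2 without array 2 of TGF-β1 then PGE2, and it was 3 without array 1 of that group or without control array 2 or 3. For unfolded protein response genes the adjusted p of 0.014 (adjusted p = 0.21 with an estimated correlation) became 0.0757 without array 1 of TGF-β1 then PGE2 and 0.0981 with cyclic loess. In all, 983 genes were higher and 1646 lower than control, 239 and 189 of them by at least 2-fold. The higher share of 37.4% became 52.7% with median centring and 47.6% with cyclic loess. The higher count was 617 without array 2 and 633 without array 1 of TGF-β1 then PGE2, 649 without control array 2 and 1605 with array weights. The lower count was 901 without array 1 and 1009 without array 2 of TGF-β1 then PGE2. Of the genes TGF-β1 raised, 436 were still higher than control after PGE2, and of those it lowered, 960 were still lower.

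The effect of PGE2 differed with prior TGF-β1 in 3014 genes, 1783 with a higher and 1231 with a lower change after TGF-β1 than without it. The largest measured positive differences were those of ADH1B (6.19 ± 0.36, adjusted p = 2.8e-06), PLXNC1 (5.11 ± 0.39), GALNT15 (4.89 ± 0.51) and the potassium channel KCNJ2 (4.41 ± 0.35). PLXNC1 changed by −1.34 with PGE2 alone and 3.77 after TGF-β1, and KCNJ2 by −2.19 and 2.21. The largest measured negative differences were those of RGS4, a regulator of G protein signalling (−5.95 ± 0.69, adjusted p = 0.00019), the cartilage matrix protein MATN3 (−5.56 ± 0.49), NOX4 (−5.52 ± 0.42) and ID4, an inhibitor of DNA binding (−4.63 ± 0.36). At least 1 group mean of ADH1B, PLXNC1, GALNT15, MATN3 and NOX4 lay under the level of the nonspecific controls (5.79), which leaves the size and order of their differences open. NOX4 rose by 2.47 with PGE2 alone and fell by −3.06 with PGE2 after TGF-β1. TGFB1 (−1.80 ± 0.18, adjusted p = 7e-05) and PTGER2 (1.46 ± 0.19, adjusted p = 0.00039) also differed. ACTA2 had an interaction of −0.94 ± 0.30 (adjusted p = 0.054), which passed with the replicate block (0.0373), among brighter genes (0.0367), with array weights (0.023), with median centring (0.0257), without array 3 of TGF-β1 then PGE2 (0.0071), and as the mean of its probe sets (−1.76, adjusted p = 0.00053). CNN1 had one of −1.01 ± 0.38 (adjusted p = 0.11), which passed as the mean of its probe sets (−2.14, adjusted p = 0.00026) and without array 3 of TGF-β1 then PGE2 (−1.33, adjusted p = 0.0147). PTGER4 (1.07 ± 0.50, adjusted p = 0.2) passed without control array 1 (1.58, adjusted p = 0.0046). TAGLN (0.42 ± 0.31, adjusted p = 0.48), COL1A1 (0.07 ± 0.20, adjusted p = 0.9), FN1 (0.06 ± 0.09, adjusted p = 0.78), COL3A1 (−0.01 ± 0.09, adjusted p = 0.96), POSTN (−0.27 ± 0.58, adjusted p = 0.86), CCN2 (−0.02 ± 0.31, adjusted p = 0.98) and PTGS2 (−1.56 ± 0.72, adjusted p = 0.19) did not pass, and the signs for COL1A1, FN1, COL3A1, POSTN and CCN2 were not stable between settings. The higher share of 59.2% became 38.8% with median centring, which moved the median of all genes from 0.01 to −0.11.

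By list, 15 of 20 unfolded protein response genes had a lower PGE2 effect after TGF-β1 and none a higher one, including CALR (−1.46 ± 0.20), TRIB3 (−1.44), XBP1 (−1.36) and DNAJB9 (−1.01), or 18 and 0 adjusted over the list alone. The unfolded protein response list had a camera adjusted p of 5.6e-14, and adjusted p = 0.0047 with an estimated correlation. Genes of the amino acid list were lower in 8 of 15, including CHAC1 (−1.79), SLC7A5 (−1.48), PYCR1 (−1.46) and PSPH (−1.36), or 11 lower and 1 higher adjusted over the list alone. Amino acid genes had an adjusted p of 2e-06, and adjusted p = 0.4 with an estimated correlation. TGF-β targets were lower in 11 of 21, including PMEPA1 (−3.05), ID1 (−2.72) and IL11 (−2.23), and higher in 4 (2 without PGE2 array 2 or array 3 of TGF-β1 then PGE2), or 12 and 5 adjusted over the list alone. The size of the PMEPA1 difference is open, since its control mean lay under the level of the nonspecific controls (5.79). TGF-β targets had an adjusted p of 0.00098, and adjusted p = 0.4 with an estimated correlation. Collagen processing enzymes were lower in 7 of 19, including PLOD2 (−1.26) and P3H1 (−1.19), and PCOLCE was higher (1.09), or 8 and 2 adjusted over the list alone. Collagen processing enzymes had an adjusted p of 0.00098, and adjusted p = 0.4 with an estimated correlation. Collagens were lower in 8 of 21, including COL15A1 (−4.39) and COL7A1 (−1.12), and higher in 4, including COL14A1 (1.85), with 9 and 4 adjusted over the list alone. COL15A1 had a control mean under the level of the nonspecific controls (5.79), which leaves the size of its difference open. For collagens the adjusted p of 0.021 (adjusted p = 0.55 with an estimated correlation) became 0.0529 without array 2 of TGF-β1 then PGE2, 0.0738 with median centring and 0.0641 with fry. Oxidative stress genes were higher in 5 of 19, including SOD3 (1.40), and SRXN1 was lower (−0.53, a call lost when any 1 of 7 arrays was left out, with an adjusted p of up to 0.0608 without control array 2), with 6 and 1 adjusted over the list alone. For oxidative stress genes the adjusted p of 0.021 (adjusted p = 0.5 with an estimated correlation) became 0.0775 without control array 1, 0.0751 without PGE2 array 3, 0.108 without TGF-β1 array 3 and 0.062 without array 1 of TGF-β1 then PGE2. Contractile genes moved both ways, with MYH11 (−2.51) and TNS1 (−1.98) among 4 lower (2 without control array 1 or 2, PGE2 array 3, TGF-β1 array 1 or 3 or array 1 of TGF-β1 then PGE2) and SYNPO2 (2.17) among 3 higher of 22 (list adjusted p = 0.27). Of genes called in both PGE2 comparisons, 136 rose with PGE2 alone and fell with it after TGF-β1, and 270 fell and then rose. TGF-β1 had raised 134 of the 136 and lowered 267 of the 270, so nearly all are among the reversed genes counted above. The counts of 136 and 270 were not set against those of independent lists.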

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

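The tests of a batch shared by replicate number, of epithelial cells in the cultures and of a linear trend with the 3' minus 5' difference, and the split of the pseudogene test by gene, were chosen only after the result was seen.

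The effect of PGE2 differed between cells with and without prior TGF-β1 in 1783 genes upward and 1231 downward, by a test of the interaction. The named genes were ADH1B (6.19), PLXNC1 (5.11), GALNT15 (4.89), KCNJ2 (4.41), RGS4 (−5.95), MATN3 (−5.56), NOX4 (−5.52), ID4 (−4.63), TGFB1 (−1.80) and PTGER2 (1.46), all as log2, and the median of the unfolded protein response list was −0.53. Of 100 regroupings of the 12 arrays, the real one included, 2 gave as many as the 3014 genes of the real grouping. The highest other, 4329, kept control and TGF-β1 whole and mixed PGE2 with TGF-β1 then PGE2, so it reflects the structure of the samples. Regroupings that mix groups widen the spread within them, and 90 of the 100 gave 0 genes. For each comparison of 3 against 3 arrays, 1 of 10 splits gave as many genes, which is too few splits for a share under 0.05. The real counts, fitted on those 6 arrays, were 4382 for TGF-β1 against control, 4144 for PGE2 after TGF-β1, 2922 for PGE2 alone and 2314 for both treatments against control, and the highest other was 0 in each, with limma. Each other split mixes the 2 groups compared, which widens the spread within its parts, so counts of 0 there do not measure chance. The labels do not say whether equal replicate numbers share an experiment. For PGE2 alone and PGE2 after TGF-β1, whose same-numbered arrays correlated, the 4 splits that part every same-numbered pair also had a highest other of 0. The counts with the replicate block were 1764 and 2685 genes higher.

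Probe sets without a single gene name, which no comparison above used, also carried a signal. Of 4040 such probe sets, 735 passed between TGF-β1 and control, 673 between TGF-β1 then PGE2 and TGF-β1, and 447 between PGE2 and control. Groups of 3 were not tested for single arrays far from the others.

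Arrays with the same replicate number deviated from their group means together, with a mean correlation of 0.313. The tables argue against a bias in overall intensity, since the mean was 0.3047 after median centring and cyclic loess. RNA degradation cannot be told apart, because the first component of the deviations followed the 3' minus 5' difference at r = −0.5914 over 12 arrays (permutation p = 0.0864), between the bounds set in advance. A culture or processing batch shared by number stays open. That 1 numbering of the arrays within groups, the real one, gave a mean as high (highest other 0.278) restates the pattern and does not test its cause. No biological explanation was tested.

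KRT7 and KRT18 rose with TGF-β1 (4.27 and 3.13) and fell with PGE2 after it. In control KRT7 stood at 4.78 and KRT18 at 5.64, under the level of the nonspecific controls (5.79), as did KRT18 after both treatments (5.65). The size of these changes is therefore open. The values argue against epithelial cells in the TGF-β1 cultures in numbers that would raise the other epithelial markers. The upper 95% limit of the median change of these 10 was 0.06566, by a bootstrap over the genes. KRT8, an abundant partner keratin, stood at 4.57 in control and 4.52 in TGF-β1. EPCAM, CDH1, KRT5, KRT8, SFTPB and ESRP1 stood under the level of the nonspecific controls (5.79) in every group, where a small rise would not show. Probe sets shared with pseudogenes stay open, although 1 of 1 probe sets of KRT7 and 2 of 2 of KRT18 rose and fell past the threshold. The bound set in advance was wrong, because a single probe set of KRT7 only restates the pattern and because the 2 KRT18 probe sets are of a type that can match other transcripts and would rise together with such a transcript. Induction in the fibroblasts themselves may also account for the rise and was not tested apart.

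Of 20 unfolded protein response genes, 14 rose with PGE2 alone, while 8 fell and 1 rose with PGE2 after TGF-β1 (adjusted p = 0.012, and 0.17 with an estimated correlation), with a median interaction of −0.53. The genes that rose and those that fell were not all the same. XBP1 (0.60 with PGE2 alone and −0.76 after TGF-β1) and DNAJB11 (0.69 and −0.24) changed direction, while TRIB3 and DDIT3 fell in both settings. The lowest median of 10000 random lists matched on mean expression was −0.3534, which argues against a shift shared by genes of like intensity. The random genes were not matched on their response to the treatments, so compression of genes that both treatments raise stays open. A single array is argued against, since at least 13 of the 15 genes with a lower interaction kept that call whichever array was left out. A linear trend with the 3' minus 5' difference is argued against as the whole cause, since the adjusted p was 2.221e-13 with it as a covariate, which moved the genes higher with PGE2 alone from 1431 to 888. A candidate explanation, as a hypothesis found and tested on the same data, is that prior TGF-β1 changes how these genes respond to PGE2, while forms of RNA quality that the difference over 2 control transcripts does not follow stay open. A batch shared by replicate number is ruled out by the design where it shifts all arrays of a number alike, since every group holds each number once and such a shift cancels from the differences between groups. The replicate block (adjusted p = 2.506e-12) therefore tested nothing, and a batch that acted differently between groups stays open.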

How the results depend on the processing

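The fit with the 3' minus 5' difference as a covariate was chosen only after the data were seen, and the other tests were planned. Counts of called genes are given as higher and lower. Testing every probe set on its own, which counts probe sets rather than genes, gave 5348 and 5786 for TGF-β1 against control, 4559 and 5218 for PGE2 after TGF-β1, 3196 and 4009 for PGE2 alone, 2230 and 2986 for both treatments against control, 3260 and 3011 for the interaction, and 3527 raised then lowered and 3100 lowered then raised. Asking for 1.5-fold, which by construction lowers counts, gave 867 and 1394, 1081 and 868, 607 and 894, and 469 and 570 in the same order, 706 lower for the interaction, and 543 and 713 for the reversals. Median centring gave 3628 higher for TGF-β1, 2079 lower for the interaction and 2194 raised then lowered, because it shifts the median of all genes (to 0.09 for TGF-β1). Array weights gave 1605 higher for both treatments against control, and the covariate 888 higher for PGE2 alone; the cause was not tested. Leaving out 1 array gave 617 to 970 higher and 901 to 1495 lower for both treatments against control, with fewer arrays, and left the other counts within 1.5 times. The slope lay between 0.155 and 0.193 without 1 array and between 0.168 and 0.182 otherwise. Signs turned only for changes that had no call: PTGER2 with PGE2 alone (0.0486 for the mean over probe sets, 0.0268 median centred, −0.134 to 0.0541 without 1 array), COL3A1 with PGE2 after TGF-β1 (−0.0061 median centred), CCN2 with PGE2 alone (−0.496 to 0.0146 without 1 array) and PTGER4 after both treatments (−0.28 to 0.639). For the interaction they were COL1A1 (−0.0446 mean over probe sets, −0.0477 median centred, −0.0395 to 0.248 without 1 array), FN1 (−0.0438 and −0.0571), CCN2 (0.0213 with array weights, −0.287 to 0.224 without 1 array), COL3A1 (−0.0664 to 0.0309) and POSTN (−0.61 to 0.196); the cause was not tested. Of 3462 values of named genes without 1 array 197 lost their call, and of 484 with the covariate 25 did. Between TGF-β1 and control the replicate block moved the adjusted p of the cyclic AMP list to 0.0693, of the lipid list to 0.0552 and of PTGS2 to 0.0375, and after both treatments that of FN1 to 0.0497. Besides these and the values given with the results, the block changed no other call of a named gene or a list, but it moved the counts of called genes. Of 120 list results 41 had a call, and 35 of these lost it with an estimated correlation. With fry, which asks a different question, 1 lost its call (collagens for the interaction, 0.0641) and 20 gained one. The mean over probe sets, which averages in weaker probe sets, lowered 120 of 454 called values of named genes by over 1.5 times and raised 5. It is given above only for genes of the panel, so other named changes may also be smaller by it. Of 484 values of named genes 11 lost their call with that mean, and of 391 in fits of only the groups compared 22 did. Signal near the floor or ceiling limits what the arrays can show, as for CDH1 at 3.96 and CXCL6 at 3.95, under the 5.79 of the nonspecific controls, and FN1 at 12.71 in control.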

Other observations

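The test in this part was chosen before its result was seen.

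PGE2 alone raised ID1 (3.87) and ID3 (3.17), which bone morphogenetic proteins (BMP) also induce. A wider rise of BMP target genes was tested as a hypothesis, and 0 of 7 other BMP target genes were higher in PGE2 than in control with limma. NOG was lower (−0.48, adjusted p = 0.0397) and MSX1 had the largest positive change (0.29, adjusted p = 0.0699). ID4 (2.73, adjusted p = 2.2e-05) and ID2 (0.55, adjusted p = 0.00023), which were not among the 7, rose as well. SMAD9, HEY1 and DLX5 stood under the level of the nonspecific controls (5.79), so the count argues only against a rise shared by the other 4 genes, and a BMP response limited to ID genes stays open.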
